A study of Rattus norvegicus with 16 samples.

How the data were processed

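Gene expression was measured in liver pieces of male Wistar rats with a 1-colour Affymetrix whole-transcript array. The rats received either untreated feed or feed with 3000 ppm phenformin, a biguanide, for 3 or 14 days, which gives 4 groups of 4 arrays. The titles of the samples call the arrays of a group biological replicates, so each array was taken as 1 animal. The labels state 5 animals per group, and 4 per group are analysed here. They also state shared cages, and which animals shared one is not given in the sources used here. Groups and replicate numbers were taken from those titles. The hour of necropsy is not given in the sources used here.

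The deposited table holds 1 intensity per probe set and array, and per the submitters' processing notes the values were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set. The deposited intensity values are on a linear scale, although RMA itself gives log2 values. Their median lay between 30.89 and 34.46 on the 16 arrays and their maximum between 987898 and 999973, so that the highest log2 value was 19.93. The program that ran RMA, its version and any further transformation of the scale are not given in the sources used here. A range this wide leaves open whether the scale was stretched after scanning, so folds are ratios of the deposited values and may not equal ratios of RNA amounts. Close to the top of the scale the spread narrows: 20 genes had a mean within 0.5 log2 units of the highest value, among them Alb, C3 and the mitochondrially encoded COX1, and changes of such genes cannot be read from these values.

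The table has 68842 probe sets. A table of probe genes from the array's annotation paired 23446 of them with 1 gene symbol and 505 with several, and 44891 were unnamed here. Probe sets with several symbols or none were left out of gene counts. Where a gene had more than 1 probe set (1182 genes), the one with the highest mean over all arrays stood for it, which left 22093 genes. For 98.6% of 22031 probe sets, the chromosome in the identifier was the one that a table of the GRCr8 assembly gives for the gene. It was not for 313, including the probe sets named Cyp2b1, Marco and Ccnb2, whose values are therefore of uncertain identity. Coordinates are not given because the build behind the probe sets is not named in the sources used here. No pair of arrays held more than 6 equal values.

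Detection calls were not used here, so a gene near the bottom of the scale may not stand above background, and its fold can then be too small. Values were converted to log2 with no pseudocount and no filter, because the deposited unit was linear intensity. A linear model with 4 group means was fitted to each gene over all 16 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, 15.15 with the prior). Contrasts compared phenformin with control livers at day 3 and at day 14, the 2 effects with each other (the effect at day 14 minus that at day 3), and control livers at day 14 with those at day 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22093 genes. The day-3 and day-14 comparisons share no arrays. Unless another fit or setting is named, every adjusted p of a gene given in the text is from this limma fit. Intervals of folds are 95% intervals from the moderated spread, which takes the spread of a gene as equal in the 4 groups. Where a compared group spread more, intervals can be too narrow and p too small. This applies to Nr1d1 in treated and Pnpla3 in control livers of day 3. The number of arrays limits the precision.

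Before the data were examined, 37 gene lists were fixed: 24 of pathways and 13 of cell types that a liver piece can hold. Of their 547 entries, 505 were measured as genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 37 lists of a comparison. The same test with a correlation estimated from the data was run beside it, and members were counted as called over all genes and adjusted over the list alone. Running camera on the control livers' time comparison was added after the data were examined. Genes named in the text follow a rule fixed in the same way: the 8 largest rises and the 8 largest falls among calls with no overlap of the 8 arrays (4 per direction for the other contrasts, of which the comparison of effects carried no condition on overlap), placeholder symbols left out. Added to these are up to 3 members with the smallest p in the direction of each list past its threshold, and at both days Pck1, G6pc1, Fgf21, Gdf15, Cyp7a1, Cyp2b1 and Cyp1a1. A further result under this rule is not reported here. Names outside the rule are marked as chosen after their values were seen.

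The alternatives tried were an intensity trend with a robust prior, a filter on the lower part of the genes by mean value, quantile normalization of the deposited values, centring of each array on its median, a fit of only the groups compared, array weights, the mean of all probe sets of a gene, the replicate number as a block, stricter thresholds and leaving out each array in turn. Centring each array on its median moved the median of all genes by less than 0.1 log2 units. The code was tested on simulated data made from the real genes' means and residual spreads, with 200 of 22093 genes changed. For the day-3 contrast 83 of 100 genes changed by 1 log2 unit and 98 of 100 changed by 2 were recovered. For the day-14 contrast these were 91 and 100 of 100, for the difference of effects 69 and 96, and for the control livers' time comparison 87 and 97. The simulation has no correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.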

Results

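The data are 16 liver expression profiles, 4 per group, from rats on control feed or on feed with 3000 ppm phenformin, killed at day 3 or day 14. Phenformin is a biguanide, a class of glucose-lowering drugs known to inhibit respiratory complex I. The sources give no aim beyond the design. The comparisons ask which liver genes differ with the drug at each time, whether the effect differs between the times, and how control livers differ between the times. The median intensity of an array lay between 30.89 and 34.46. Values are means of log2 intensity ± SD (n = 4 arrays per group) and folds carry their 95% interval.

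After 3 days of phenformin the livers held less mRNA of cell division genes, collagens and other fibroblast genes, and of the clock repressors Per2, Cry1 and Bhlhe40, and more of Nr1d1, Cyp8b1 and Asl. Nr1d1, a nuclear receptor that represses clock genes, rose from 5.33 ± 0.10 to 9.14 ± 1.81, or 14.0-fold (5.82 to 33.8; adjusted p = 0.00757). Its control values lay below the level of the median gene (5.86), and detection calls were not used here, so background signal can make this fold too small. Inmt, an indolethylamine methyltransferase, rose 14.1-fold (5.42 to 36.7), and Cyp8b1, the hydroxylase that directs bile acid synthesis to cholic acid, rose 7.45-fold (3.23 to 17.2; adjusted p = 0.0203). Among calls with no overlap of the arrays, the next largest rises were those of Serpina7, the thyroxine-binding globulin (4.21-fold), and Il1r1, an interleukin-1 receptor (2.97-fold). They were followed by Asl of the urea cycle (2.52-fold, 1.87 to 3.41), Gnmt, a methyltransferase of glycine (2.47-fold), and the transcription factor Stat3 (2.38-fold). Pnpla3, a lipid droplet hydrolase, fell from 10.51 ± 2.01 to 6.64 ± 0.83 (14.7-fold, 4.99 to 43.0; adjusted p = 0.0181), Bhlhe40 was 5.00-fold lower (2.35 to 10.6), and Tsku, a secreted leucine-rich protein, was 4.63-fold lower (2.90 to 7.37; adjusted p = 0.00622). For Pnpla3 the control livers of day 14 stood at 6.98 ± 0.75, near the treated livers of day 3. For Inmt they stood at 11.03 ± 1.41, between the control (8.95) and treated livers (12.77) of day 3. In all, 55 genes were called higher and 199 lower, of which 36 and 146 differed by at least 1.5-fold. An unadjusted p under 0.05 was found for 2351 genes, where chance gives 1105.

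Cell cycle and DNA replication genes formed the largest called group at day 3. Of 32 measured members, 22 fell, 0 rose and 10 did not pass (31 fell adjusted over the list alone), and the list as a whole was lower by camera (median log2 change -0.93, adjusted p = 1.35e-47; adjusted p = 0.033 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 11.24 ± 0.54 to 6.99 ± 1.04 (19.0-fold, 7.17 to 50.4). The proliferation marker Mki67 was 7.17-fold lower and Top2a, which untangles replicated DNA, 6.74-fold lower. The cell cycle kinases Cdk1 and Aurkb were 2.27-fold and 1.99-fold lower and the replication helicase gene Mcm5 was 1.69-fold lower. Treated values of these 3 genes (4.79, 4.73 and 4.83) lay below the median probe set of each array, so background signal can make their folds too small. Rrm2l1 was 20.5-fold lower and the cytoskeleton-associated gene Ckap2 5.33-fold lower. Both have genes of similar name with which their probes may share transcripts. Sequences were not compared, so the identity of both is uncertain. Rrm2l1 and Rrm2 may therefore not be separate results. The mean of the list stood at 7.14 ± 0.16 in control livers at day 3, 6.05 ± 0.28 in treated livers at day 3, 6.10 ± 0.28 in control livers at day 14 and 6.26 ± 0.35 in treated livers at day 14, so the group that stood apart was the control livers of day 3. Markers of stellate cells and fibroblasts moved alongside: 5 of 11 fell, 0 rose and 6 did not pass (8 fell adjusted over the list alone), with a camera adjusted p of 3.9e-14 (adjusted p = 0.000903 with an estimated correlation). Among them the collagens Col1a1 and Col1a2 fell 1.73-fold (1.46 to 2.03) and 1.77-fold (1.46 to 2.15), and the matrix proteoglycan gene Lum fell 2.37-fold (1.81 to 3.12). That list's mean was 8.73 ± 0.11 in control and 8.15 ± 0.05 in treated livers at day 3, against 8.37 ± 0.05 and 8.36 ± 0.08 at day 14. For Lum the treated mean at day 3 (4.56) lay below the median probe set of each array, so background can make its fold too small.

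**Figure D1:**
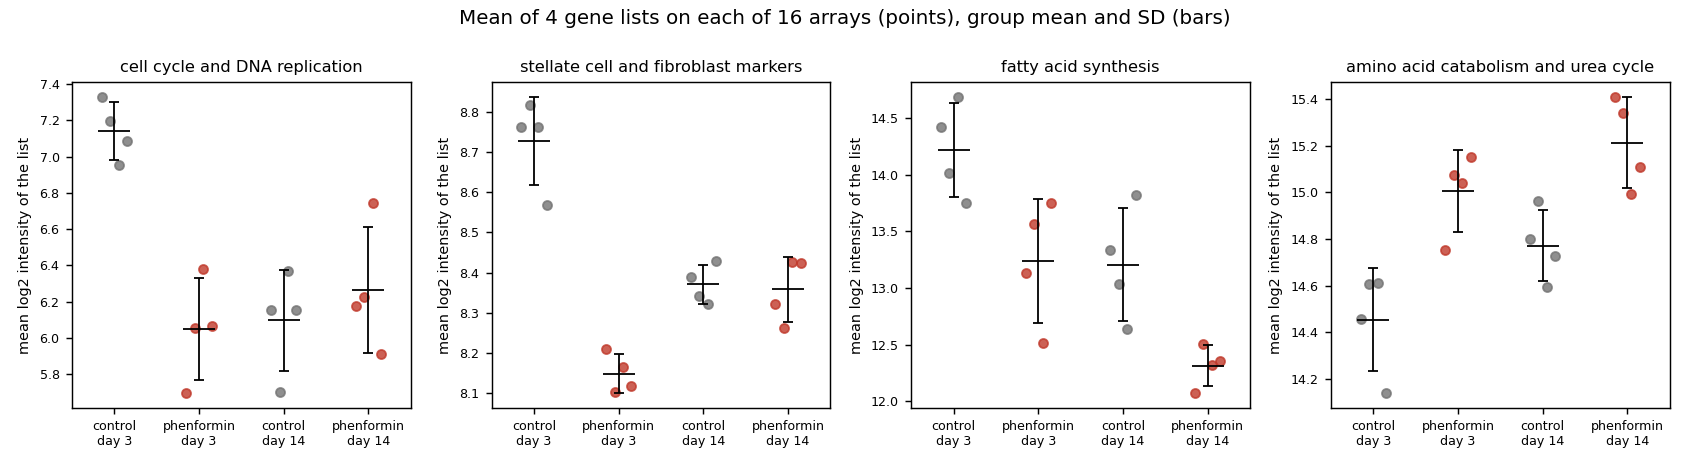
Mean log2 intensity of 4 fixed gene lists on each of the 16 arrays. Points are arrays, grey for control and red for phenformin, and bars give the group mean and SD. In the cell cycle list the control livers of day 3 average 7.14 and the other groups 6.05 to 6.26. In the amino acid list the treated livers average 15 at day 3 and 15.21 at day 14, against 14.45 and 14.77 in controls.

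Among metabolic lists at day 3, amino acid catabolism and the urea cycle stood higher, with 3 of 19 members rising, 0 falling and 16 not passing (13 rose adjusted over the list alone; camera adjusted p = 7.77e-13; adjusted p = 0.0748 with an estimated correlation). The 3 were Asl, the glutaminase gene Gls2 (1.96-fold, 1.59 to 2.42) and Agxt, an aminotransferase of glyoxylate (2.06-fold, 1.48 to 2.87). Fatty acid synthesis stood lower, with 2 of 18 falling, 0 rising and 16 not passing (5 fell adjusted over the list alone; camera adjusted p = 3.34e-09; adjusted p = 0.176 with an estimated correlation). These 2 were Pnpla3 and the elongase gene Elovl5 (1.55-fold, 1.27 to 1.90), while Elovl6 was 4.98-fold lower (2.06 to 12.1) without passing (adjusted p = 0.0959). The value of Elovl6 comes from 1 of its 3 probe sets, whose identifier gives no chromosome, so its identity was not checked. Cholesterol synthesis and uptake had 1 of 17 falling and 0 rising (5 fell adjusted over the list alone; camera adjusted p = 5.66e-07; adjusted p = 0.176 with an estimated correlation). That gene was Pmvk of the mevalonate pathway (1.5-fold, 1.25 to 1.81), with Insig1 at -1.25 ± 0.38 (log2 change ± SE, adjusted p = 0.167) and Sc5d at -0.44 ± 0.13 (adjusted p = 0.175). In both of these lists the control livers of day 3 stood above the other groups. The mean of the cholesterol list was 11.50 ± 0.18 in them, against 11.12 ± 0.24 in treated livers of day 3 and 11.14 ± 0.07 and 11.18 ± 0.23 in control and treated livers of day 14. The mean of the fatty acid list was 14.22 ± 0.42, against 13.24 ± 0.55, 13.21 ± 0.50 and 12.32 ± 0.18. Glycolysis genes had 0 of 20 past the threshold (3 fell adjusted over the list alone) and a camera adjusted p of 0.00636 (adjusted p = 0.317 with an estimated correlation). Pgk1 changed by -0.47 ± 0.12, Pklr, the liver pyruvate kinase gene, by -1.09 ± 0.33 and Pgam1 by -0.24 ± 0.08, with adjusted p of 0.0751, 0.18 and 0.211.

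In the circadian clock list 1 of 17 members rose, 4 fell and 12 did not pass at day 3 (2 and 5 adjusted over the list alone; camera lower, adjusted p = 0.00496; adjusted p = 0.107 with an estimated correlation). Per2 fell from 7.96 ± 0.40 to 6.24 ± 0.34 (3.32-fold, 2.38 to 4.62; adjusted p = 0.00501) and Cry1 3.14-fold (2.11 to 4.67). The fourth fall, beside Bhlhe40, was that of Per1 (-1.61 log2 units), a gene chosen after its values were seen. The hour of necropsy, on which levels of clock genes depend, is not given in the sources used here, and 1 treated array (replicate 4) lay far from the others for Per2. Markers of periportal and of pericentral hepatocytes both stood higher by camera (adjusted p = 0.0137 and 0.0333; adjusted p = 0.268 for each with an estimated correlation). Of the periportal list only Gls2 rose among 10, with 0 falling, and Ass1 (0.29 ± 0.10) and Hal (0.50 ± 0.18) did not pass. Of the pericentral list 0 of 10 passed, with Cyp2e1 at 0.50 ± 0.17, Oat at 0.94 ± 0.32 and Slc1a2 at 0.94 ± 0.33. Adjusted over the list alone, 4 periportal markers rose and 0 fell, and 4 pericentral markers rose and 1 fell. Gls2, Ass1, Hal and Oat are also in the amino acid list. Macrophage markers had 0 of 12 past the threshold, over all genes or over the list alone, and a camera adjusted p of 0.0359 (adjusted p = 0.764 with an estimated correlation). Csf1r was at 0.65 ± 0.32, Clec4f at 0.38 ± 0.29 and Marco, whose probe set is of uncertain identity, at 0.57 ± 0.48.

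Genes often followed under biguanides did not pass at day 3. The gluconeogenic genes Pck1 and G6pc1 changed by -0.25 ± 0.48 and -0.89 ± 0.45 (adjusted p = 0.935 and 0.527), the stress hormone genes Fgf21 and Gdf15 by 0.09 ± 0.18 and -0.08 ± 0.23 (0.941 and 0.957), and the cytochromes Cyp2b1 and Cyp1a1 by -0.29 ± 0.60 and 0.34 ± 0.64 (0.94 and 0.934). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 15.31 ± 0.67 in control and 12.51 ± 1.22 in treated livers, a change of -2.80 ± 0.79 that did not pass (adjusted p = 0.132). The identity of the Cyp2b1 probe set is uncertain. Fgf21 stood at 5.32 in control and 5.40 in treated livers, below the median gene (5.86), and Gdf15 at 6.31 and 6.23. Background signal can hide a change at these levels. None of the 34 measured nuclear genes of complex I passed (camera adjusted p = 0.169), nor did any of 31 genes of complexes II to V (0.0769), 9 gluconeogenesis genes (0.719), 24 genes of the ATF4 stress response (0.996) or 9 genes of AMPK subunits and biguanide transporters (0.739). In the other lists without a camera call, single members passed: Cyp8b1 of the bile acid list (camera adjusted p = 0.0641) and Stab2 of the endothelial markers, a gene chosen after its values were seen, which fell by 0.56 log2 units (camera adjusted p = 0.115).

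The day-3 counts depended on single arrays. Leaving out control replicates 1, 2, 3 and 4 of day 3 in turn gave 17, 18, 22 and 34 genes higher and 85, 94, 143 and 158 lower. Leaving out treated replicates 1, 2, 3 and 4 gave 23, 31, 17 and 46 higher and 96, 118, 134 and 166 lower. Of the 32 cell cycle genes, 11, 12, 19 and 17 were called lower without those control arrays and 11, 13, 22 and 16 without those treated arrays. Calls of Il1r1 and Stat3 were lost in 11 of 16 such fits each, Bhlhe40 in 10, Agxt in 8, Elovl5 and Pmvk in 7 each, Serpina7 and Gnmt in 6 each, Cyp8b1 in 5, and Pnpla3, Mki67 and Ckap2 in 3 each (highest adjusted p = 0.155, Stat3 without control replicate 2). In a fit of the day-3 arrays alone Nr1d1, Cyp8b1, Serpina7, Il1r1, Stat3, Pnpla3 and Elovl5 did not pass (adjusted p = 0.0651, 0.0779, 0.061, 0.139, 0.0804, 0.11 and 0.0935). The call of Elovl5 also ended with quantile normalization (0.228) and that of Stat3 with centring (0.0657). List calls ended for glycolysis without control replicate 3 (adjusted p = 0.0519), for macrophages without control or treated replicate 2 (0.558 and 0.771), with array weights (0.132) and in the fit of the day-3 arrays alone (0.0586), for pericentral markers without control or treated replicate 3 (0.076 and 0.0855) and for periportal markers without control or treated replicate 4 (0.0686 and 0.0818).

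After 14 days Nr1d1 and Cyp8b1 showed the largest rises among genes called, and Bhlhe40, Per2 and Cry1 stood lower, together with Csad, Ppp1r3b and Pklr. Nr1d1 rose from 5.70 ± 0.13 to 9.96 ± 0.52 (19.2-fold, 7.97 to 46.3; adjusted p = 0.0063) and Cyp8b1 from 11.27 ± 0.84 to 15.22 ± 0.63 (15.4-fold, 6.67 to 35.6; adjusted p = 0.00806). Sdr42e1, a short-chain dehydrogenase, rose 4.94-fold (3.11 to 7.84), Aldh1a1, a retinaldehyde dehydrogenase, 4.46-fold (2.50 to 7.95) and Asl 3.18-fold (2.36 to 4.30). The flippase subunit gene Tmem30b rose 2.72-fold, the splicing factor gene Mbnl3 2.62-fold and the bicarbonate transporter gene Slc4a4 2.58-fold. For Aldh1a1 the control livers of day 14 stood lowest, at 10.67 ± 0.96 against 12.83 ± 0.22 in treated livers. At day 3 its control and treated livers stood at 11.94 ± 0.69 and 12.56 ± 0.27. Csad, the decarboxylase of taurine synthesis, fell from 13.95 ± 0.29 to 11.57 ± 0.75 (5.19-fold, 3.41 to 7.90; adjusted p = 0.00329). Ppp1r3b, which targets a phosphatase to glycogen, was 4.56-fold lower (3.15 to 6.61), Pklr 4.36-fold (2.67 to 7.14), the cell cycle inhibitor gene Cdkn1a 4.36-fold (2.54 to 7.48) and Tsku 3.66-fold (2.29 to 5.82). The calls numbered 32 higher and 39 lower, 24 and 31 of them by at least 1.5-fold, and 2484 genes had an unadjusted p under 0.05, where chance gives 1105.

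**Figure D2:**
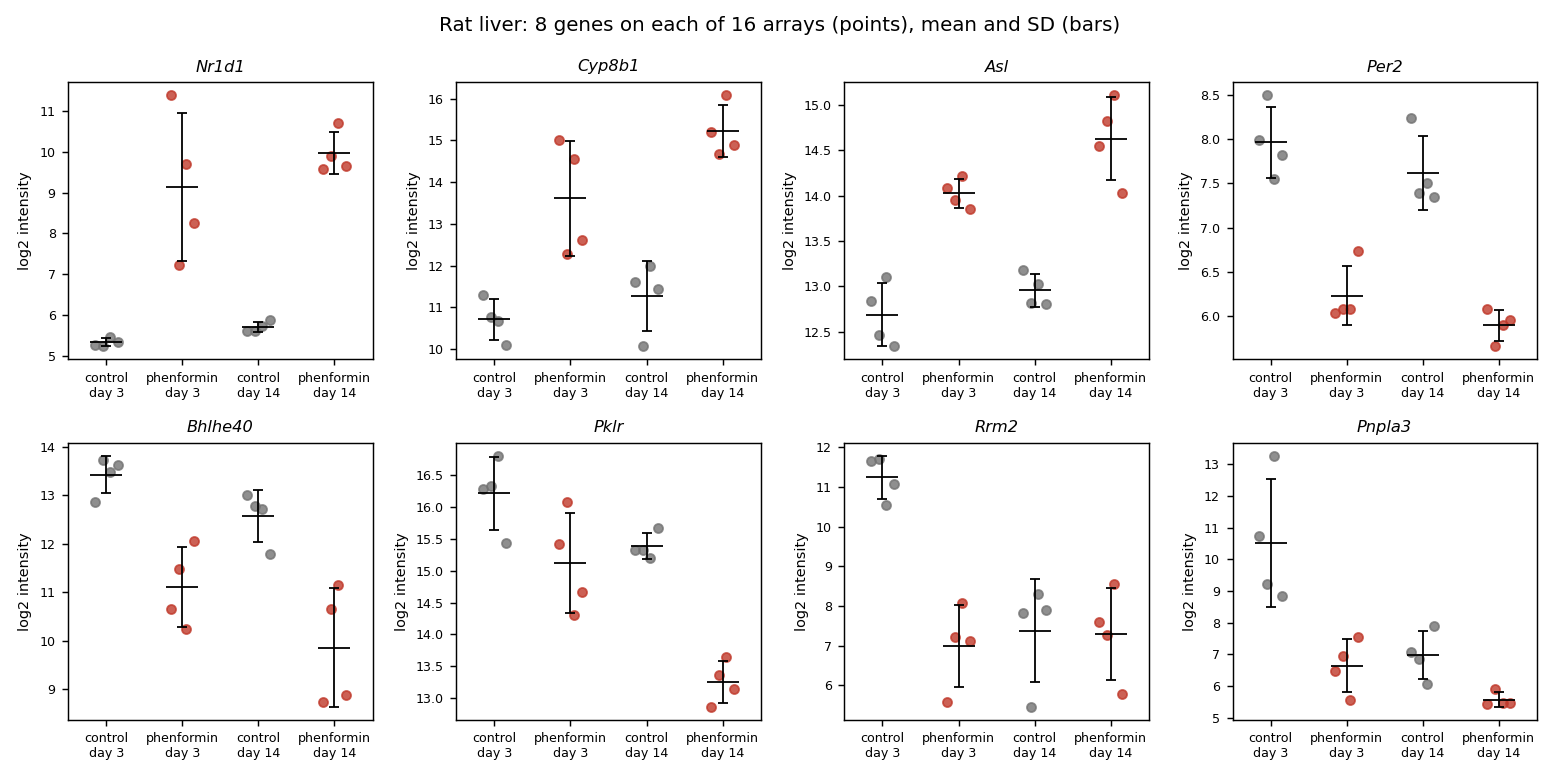
Log2 intensity of 8 genes on each of the 16 arrays. Points are arrays, grey for control and red for phenformin, and bars give the group mean and SD. Nr1d1 averages 9.14 and 9.96 in treated livers at day 3 and day 14, against 5.33 and 5.70 in controls, while Rrm2 averages 11.24 in control livers at day 3 and 6.99 to 7.37 in the other groups.

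The circadian list at day 14 had 1 of 17 members rising, 3 falling and 13 not passing (2 and 7 adjusted over the list alone; camera lower, adjusted p = 0.000227; adjusted p = 0.104 with an estimated correlation). Bhlhe40 fell 6.57-fold (3.09 to 14.0), and Per2 and Cry1 3.30-fold each (2.37 to 4.60 and 2.22 to 4.91). Fatty acid synthesis had 1 of 18 falling and 0 rising (5 fell adjusted over the list alone; camera adjusted p = 1.25e-07; adjusted p = 0.18 with an estimated correlation). That gene was Mlxipl, the carbohydrate-responsive transcription factor (2.00-fold, 1.5 to 2.67; adjusted p = 0.0458), and Scd (-3.26 ± 0.75, adjusted p = 0.0777) and Thrsp (-1.87 ± 0.39, adjusted p = 0.0578) did not pass. In the glycolysis list Pklr was the 1 of 20 to fall (3 adjusted over the list alone; camera adjusted p = 0.000401; adjusted p = 0.199 with an estimated correlation), with Gckr at -0.69 ± 0.14 and Pfkfb1 at -1.10 ± 0.31. In the amino acid list Asl was the 1 of 19 to rise (6 adjusted over the list alone; camera adjusted p = 2.41e-06; adjusted p = 0.18 with an estimated correlation), with Agxt at 0.90 ± 0.22 and Aass at 0.62 ± 0.15. Pericentral hepatocyte markers stood higher by camera with 0 of 10 past the threshold over all genes and 7 rising and 1 falling adjusted over the list alone (camera adjusted p = 5.49e-05; adjusted p = 0.113 with an estimated correlation). Slc13a3 was at 1.04 ± 0.23, Cyp2e1 at 0.68 ± 0.17 and Lgr5 at 0.70 ± 0.17.

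Target genes of nuclear receptors also stood higher at day 14. Of 15 CAR and PXR target genes 1, Aldh1a1, rose and 0 fell (3 rose adjusted over the list alone; camera adjusted p = 0.000401; adjusted p = 0.18 with an estimated correlation), with Ces2c at 1.30 ± 0.30 and Abcc3 at 0.93 ± 0.22. Of 21 PPARalpha target genes 0 passed (4 rose adjusted over the list alone; camera adjusted p = 0.000401; adjusted p = 0.447 with an estimated correlation), with Hadhb at 0.69 ± 0.16, Hadha at 0.52 ± 0.13 and Cpt1a at 2.57 ± 0.81. The bile acid list had 2 of 20 rising and 0 falling (4 rose adjusted over the list alone; camera adjusted p = 0.0357; adjusted p = 0.18 with an estimated correlation), namely Cyp8b1 and the organic anion transporter gene Slco1b2 (1.57-fold, 1.38 to 1.79), with Amacr at 0.88 ± 0.18 and an adjusted p of 0.0511. No member passed over all genes in the remaining lists with a camera call. These were endoplasmic reticulum chaperones, lower with 0 of 16 (Edem1 -0.74 ± 0.21, Xbp1 -0.55 ± 0.35, Sel1l -0.20 ± 0.12), hypoxia-inducible genes, lower with 0 of 17 (P4ha1 -0.62 ± 0.17, Pdk1 -0.61 ± 0.20, Vegfa -0.47 ± 0.15), erythroid markers, lower with 0 of 5 (Alas2 -0.73 ± 0.23, Hba-a1 -0.55 ± 0.24, Hbb -0.52 ± 0.23), and cell cycle genes, higher with 0 of 32 (Mcm4 0.45 ± 0.14, Tpx2 0.54 ± 0.20, and Ccnb2, of uncertain identity, 0.91 ± 0.33). Their camera adjusted p were 0.00745, 0.041, 0.00144 and 0.041, and with an estimated correlation these adjusted p were 0.386, 0.18, 0.199 and 0.834. Adjusted over the list alone, 1 chaperone, 3 hypoxia-inducible genes, 1 erythroid marker and 0 cell cycle genes passed, all lower.

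At day 14 Pck1 changed by 0.42 ± 0.48, G6pc1 by 0.80 ± 0.45, Fgf21 by -0.01 ± 0.18, Gdf15 by 0.05 ± 0.23, Cyp7a1 by -1.26 ± 0.79, Cyp2b1 by 0.89 ± 0.60 and Cyp1a1 by 0.92 ± 0.64, with adjusted p of 0.832, 0.564, 0.993, 0.971, 0.609, 0.643 and 0.665. Fgf21 stood at 5.16 in control and 5.15 in treated livers, below the median gene (5.86), and Gdf15 at 6.11 and 6.15. Background signal can hide a change at these levels. None of the 34 complex I genes passed (camera adjusted p = 0.694), and the stellate cell list stood at a median change of -0.001 with 0 of 11 past the threshold (camera adjusted p = 0.674). Cdkn1a was the 1 of 11 p53 target genes to fall (camera adjusted p = 0.524).

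Single arrays also moved the day-14 counts. Leaving out control replicates 1, 2, 3 and 4 of day 14 in turn gave 29, 16, 24 and 66 genes higher and 25, 26, 21 and 66 lower. Leaving out treated replicates 1, 2, 3 and 4 gave 74, 15, 13 and 12 higher and 48, 19, 17 and 18 lower. A fit of the day-14 arrays alone called 8 higher and 15 lower. In it Aldh1a1, Tmem30b, Slc4a4, Bhlhe40, Tsku, Cry1 and Mlxipl did not pass (adjusted p = 0.16, 0.16, 0.158, 0.173, 0.121, 0.16 and 0.161). Without 1 array the call of Mlxipl was lost in 13 of 16 fits, Bhlhe40 in 7, Cdkn1a in 6, Aldh1a1 and Tsku in 4 each and Slc4a4 in 1 (highest adjusted p = 0.133, Mlxipl without treated replicate 3). The call of Mlxipl also ended with centring (0.0571) and with array weights (0.0706). Among lists the call for PPARalpha targets ended without treated replicate 3 of day 14 (adjusted p = 0.0744) and that for chaperones without control replicate 4 or treated replicate 3 (0.0545 and 0.0851). The bile acid call ended without control replicate 4 or treated replicates 1 or 4 (0.184, 0.101 and 0.0958), and the hypoxia call without control replicates 2 or 3 or treated replicates 1 or 2 (0.122, 0.161, 0.176 and 0.0572). The cell cycle call ended without control replicate 2 or 4 of day 14 (0.805 and 0.073), treated replicate 3 of day 14 (0.99), control replicate 2 of day 3 (0.0503) or treated replicate 4 of day 3 (0.0512). With each array centred on its median the bile acid, hypoxia and cell cycle calls ended (0.0564 each). The bile acid call also ended with array weights, where the median of the list was -0.011 (adjusted p = 0.0578), and the cell cycle call without the lower part of the genes by mean value (0.134).

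**Figure D3:**
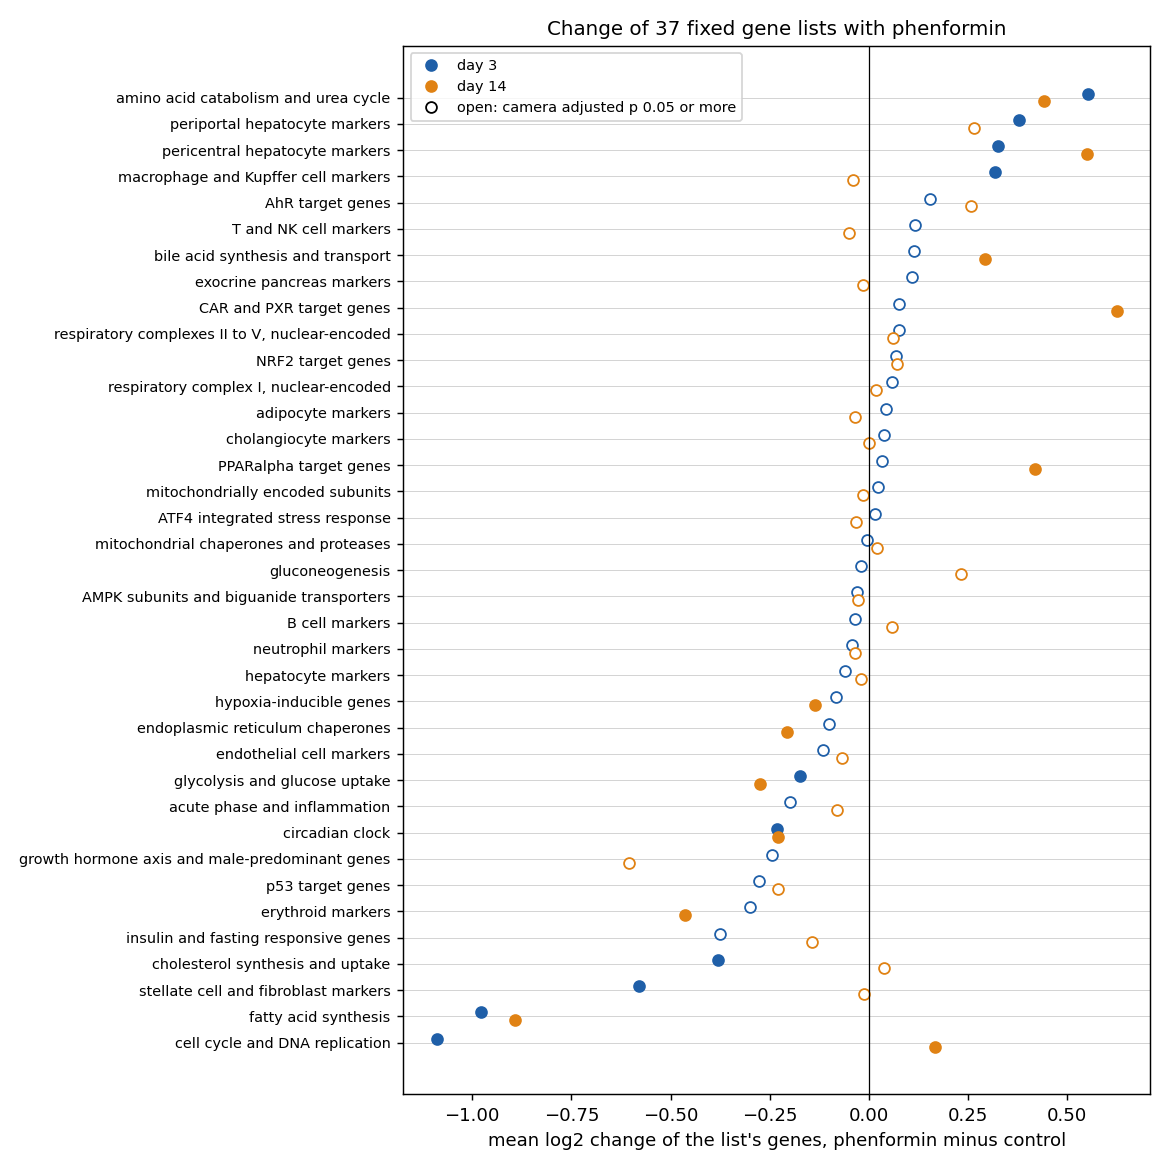
Mean log2 change of the measured genes of each of the 37 fixed lists with phenformin, at day 3 (blue) and day 14 (orange). Filled points passed camera at a preset correlation (10 lists at day 3 and 12 at day 14), open points did not. With an estimated correlation 2 lists passed at day 3 and 0 at day 14. The cell cycle list lies at -1.09 at day 3 and 0.17 at day 14, and the fatty acid synthesis list at -0.98 and -0.89.

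The calls of the 2 days overlapped. Of the genes called, 10 were higher and 16 lower at both days, where independent lists would share 0.0797 and 0.351 (two-sided Fisher's exact test, p = 2.38e-19 and 3.2e-23), and 0 were called in opposite directions. Both comparisons take the spread of a gene from the same fit, so the calls are not fully independent. Fits of each day's arrays alone shared 6 calls in place of 26. Fisher's test also takes genes as independent, although genes can change together, so its p does not measure the spread between animals. The largest shared rises were Nr1d1, Cyp8b1, Sdr42e1 and Asl, and the largest shared falls Bhlhe40, Ppp1r3b, Tsku and Per2. Of the 71 calls at day 14, 69 had the same sign at day 3. Of the 55 genes called higher at day 3, 54 had the same sign at day 14, and of the 199 called lower, 120 had. Across all 22093 genes, which are not independent replicates, the log2 changes of the 2 days correlated with Pearson's r of 0.444 and Spearman's rho of 0.331. The shared calls numbered 14, 14 and 13 without control replicates 1, 2 and 3 of day 3, and 15 and 11 without treated replicates 1 and 3 of day 3. They numbered 16 without control replicate 3 of day 14, and 16, 15 and 15 without treated replicates 2, 3 and 4 of day 14.

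The effect at day 14 was compared with that at day 3 directly. A single gene passed, Anlnl1, named as an anillin-like gene (anillin is a scaffold of cell division), which stood at 5.67 ± 0.11 and 4.35 ± 0.23 in control and treated livers at day 3 and at 4.66 ± 0.29 and 4.92 ± 0.20 at day 14. The difference of its effects was 1.58 ± 0.21 (log2 ± SE; adjusted p = 0.0284), and its probes may share transcripts with Anln. Apart from the control livers of day 3, its group means lay below the median probe set of each array. Whether they stood above background is unknown. With 1034 genes at an unadjusted p under 0.05, where chance gives 1105, single genes gave no excess. Among lists, the cell cycle genes differed (median difference 1.01, 0 of 32 past the threshold over all genes and 30 adjusted over the list alone; camera adjusted p = 1.63e-55; adjusted p = 0.0186 with an estimated correlation), with Cdk1 at 1.19 ± 0.21, Tpx2 at 1.49 ± 0.28 and Bub1 at 1.46 ± 0.28. So did stellate cell and fibroblast markers (median 0.50, 0 of 11 and 6; camera adjusted p = 2.14e-11; adjusted p = 0.00253 with an estimated correlation), with Lum at 1.24 ± 0.26, Col1a1 at 0.71 ± 0.16 and Dcn at 1.14 ± 0.30. Camera also called cholesterol synthesis (median 0.33; 0 of 17 and 2; Sc5d, Mvd and Sqle), PPARalpha targets (0.34; 0 of 21 and 0; Cpt2, Plin2 and Hadhb), CAR and PXR targets (0.50; 0 of 15 and 0; Aldh1a1, Abcc3 and Por) and macrophage markers (-0.40; 0 of 12 and 0; C1qc, Cd163 and Csf1r). Their camera adjusted p were 2.18e-06, 0.000984, 0.00433 and 0.0214, and with an estimated correlation these adjusted p were 0.288, 0.794, 0.288 and 0.921. In the cell cycle, stellate cell and cholesterol lists the control livers of day 3 had the highest mean of the groups (7.14, 8.73 and 11.50). In the macrophage list they had the lowest (9.87). The difference of effects in these lists may thus lie in the day-3 controls, and a drug effect that changed with time is not shown. For PPARalpha and for CAR and PXR targets the treated livers of day 14 stood highest (12.83 and 13.72). The single gene's call was lost without 9 of the 16 arrays in turn (highest adjusted p = 0.116, without control replicate 1 of day 3), and leaving out control replicate 3 of day 14 gave 10 genes. The list calls for PPARalpha targets ended without control replicate 3 of day 3 or treated replicate 3 of day 14 (0.0512 and 0.062) and those for CAR and PXR targets without control replicate 4 or treated replicate 3 of day 14 (0.0592 and 0.0565). The macrophage call ended without control or treated replicate 2 of day 3 (0.403 and 0.604), control replicates 3 or 4 of day 14 (0.225 and 0.0555) or treated replicates 2 or 4 of day 14 (0.172 and 0.193), and with array weights (0.16).

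Control livers differed between the days in 89 genes, 11 higher and 78 lower at day 14, with 1580 at an unadjusted p under 0.05. The largest falls were in Rrm2 (14.6-fold, 5.51 to 38.7; adjusted p = 0.0303), Rrm2l1 (17.5-fold, 5.76 to 53.3), Top2a (4.88-fold, 2.51 to 9.48) and Me1, the malic enzyme gene (4.41-fold, 2.33 to 8.33; adjusted p = 0.0476). The largest rises were in Gimap4 (2.33-fold, 1.80 to 3.01; adjusted p = 0.0165) and Gimap9 (1.54-fold), GTPase genes of lymphocytes, the taste receptor gene Tas2r107 (1.75-fold) and Gstm7 (1.52-fold). Tas2r107 (4.07 and 4.88 at day 3 and day 14) and Gimap9 (3.51 and 4.14) lay below the median probe set of each array, and whether they stood above background is unknown. Of the cell cycle list 18 of 32 fell, 0 rose and 14 did not pass (31 fell adjusted over the list alone; camera adjusted p = 1.59e-55; adjusted p = 0.0186 with an estimated correlation). Of the stellate cell and fibroblast list 2 of 11 fell, Col1a1 and Col3a1, both named here after their values were seen (4 adjusted over the list alone; camera adjusted p = 5.65e-08; adjusted p = 0.0146 with an estimated correlation). Of the fatty acid synthesis list Me1 was the 1 of 18 to fall (7 adjusted over the list alone; camera adjusted p = 2.53e-11; adjusted p = 0.161 with an estimated correlation). The day-3 controls also enter the day-3 effect of the drug, so the 2 comparisons are not independent. The count of 89 became 0, 14, 57 and 8 without control replicates 1, 2, 3 and 4 of day 3, and 24, 0 and 46 without control replicates 1, 2 and 4 of day 14. It was 37 and 35 without treated replicates 2 and 4 of day 3, 43 and 38 without treated replicates 1 and 2 of day 14, and 0 in a fit of the control arrays alone. Each of the 8 genes named here lost its call without control replicate 2 of day 14, Gimap4 at an adjusted p of 0.0572 and Gstm7 at 0.175. With centring Tas2r107, Gimap9, Gstm7 and Me1 did not pass (0.072, 0.0686, 0.0632 and 0.0561), with quantile normalization Tas2r107 and Gimap9 (0.0774 and 0.0655), and with the intensity trend Gimap9 (0.0558).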

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

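The tests of the clock and of the stellate cell markers were chosen before the values they measure were seen, and the tests of the cell cycle genes and the splits of the arrays were chosen after.

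The clock genes called at both days, with Nr1d1 higher and Per2, Cry1 and Bhlhe40 lower, go in directions that a shift of the daily phase of the livers could give, from the hour of necropsy, the time of feeding or the drug (the hour is not given in the sources used here). Dbp, Tef and Hlf, clock output genes taken to rise with Nr1d1 under such a shift, had a mean log2 change of -0.47 (SE 0.23) at day 3 and -0.39 (SE 0.23) at day 14. These means meet the bound set beforehand and argue against a shift in which the 3 genes follow Nr1d1, although the day-14 mean lies within 2 SE of 0. It rests on Hlf (-0.92 ± 0.26 at day 3 and -1.28 ± 0.26 at day 14) more than on Dbp (-0.19 ± 0.37 and 0.36 ± 0.37) and Tef (-0.30 ± 0.14 and -0.24 ± 0.14), whose mean levels of 5.96 and 6.40 lie near that of the median gene (5.86). A shift of the daily phase in which these 3 genes do not rise with Nr1d1 was not tested and stays open. A direct effect of phenformin on single clock genes was not tested either and stays open as a hypothesis.

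The fall of cell cycle genes at day 3 goes with control livers of day 3 that stood above all other groups. Treated livers of day 3 differed from the mean of the day-14 groups by -0.13 (SE 0.17; log2, mean of the list), while control livers of day 3 lay 0.96 (SE 0.17) above it. A single array does not account for it: in the fits without 1 of the 16 arrays at least 11 of the 32 members were called lower and the list stayed past its threshold. These values leave open whether phenformin lowered division that is usual in livers of this age, or whether the control livers of day 3 differ in another way, such as in cage or handling, which may not involve the drug. The labels give no batch with which to separate these.

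Stellate cell and fibroblast markers fell in the same comparison, and a lower share of these cells in the liver pieces was tested as the whole cause. Des, Lrat, Reln and Pdgfrb, which mark the cells, changed by -0.29 (SE 0.09) on average and Col1a1, Col1a2 and Col3a1 by -0.73 (SE 0.10). The difference of 0.45 (SE 0.11) argues against an equal loss of all these cells as the whole cause. Such a loss would lower both sets alike, provided that both stand above background. An unequal loss of stellate cells and fibroblasts could lower the sets by different amounts and was not tested. A smaller share together with lower collagen expression per cell may still account for the values, and a biological effect of the drug on matrix genes is a hypothesis that was found and tested on the same arrays.

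Chance assignment of the arrays was tested with other splits into groups of the same sizes. At day 3 only 1 of the 35 splits, the real one, gave as many as 254 genes (highest other 1). At day 14 only 1 of 35 gave 71 (highest other 1), and for the control livers between days only 1 of 35 gave 89 (highest other 1). Every other split mixes arrays of both groups, so that a real difference widens its spread. Low counts in those splits are therefore partly built in and do not give the number of genes that chance would call. A share of 1 of 35, the lowest this test can give, speaks against chance assignment for these counts as fitted over all 16 arrays. Chance is not excluded, because the splits take the arrays as independent although cages were shared. The count of 89 still became 0 in a fit of the control arrays alone, and without control replicate 1 of day 3 or control replicate 2 of day 14. For the difference of effects between days 5 of 100 drawn splits gave at least the 1 gene found (highest other 5). The test does not speak against chance there.

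In 19 of 460 groups of 4 arrays 1 array lay far from its 3 fellows, where chance gives about 23. Values are its gap to the nearest array divided by the range of the group. In control livers of day 14, replicate 4 stood apart for Cyp2e1 (0.938), Sqle (0.89), the mean of the circadian list (0.877), Edem1 (0.873) and Tmem30b (0.852), replicate 3 for Cpt1a (0.889) and replicate 2 for Rrm2 (0.836). In control livers of day 3, replicate 1 stood apart for Hba-a1 (0.984), replicate 3 for Slco1b2 (0.845), and replicate 4 for the mean of the circadian list (0.898) and Pck1 (0.861). In treated livers of day 3, replicate 4 stood apart for Per2 (0.937) and Pck1 (0.875). In treated livers of day 14, replicate 1 stood apart for the mean of the pericentral markers (0.869), replicate 2 for Pnpla3 (0.962), replicate 3 for the mean of the CAR and PXR targets (0.899) and Anlnl1 (0.862), and replicate 4 for Xbp1 (0.857) and Gckr (0.847).

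By a direct test, the effect at day 14 differed from that at day 3 for Anlnl1 by 1.58 log2 units, and for the median of cell cycle genes by 1.01, of stellate cell and fibroblast markers by 0.50, of CAR and PXR targets by 0.50, of PPARalpha targets by 0.34, of cholesterol synthesis by 0.33 and of macrophage markers by -0.40. None of these 6 lists had a member past limma's threshold over all genes (1034 of all genes had an unadjusted p under 0.05). The last 4 lost their calls with an estimated correlation (adjusted p = 0.288, 0.794, 0.288 and 0.921), and the macrophage call ended in 6 of 16 fits without 1 array. In the cell cycle, stellate cell and cholesterol lists, and for Anlnl1, the control livers of day 3 stood highest of the groups. In the macrophage list they stood lowest. These differences of effects may thus lie in the day-3 controls, and a drug effect that changed with time is not shown. Among 45396 probe sets with no or several gene symbols, which enter no gene count, limma called 5 at day 3 (1 higher, 4 lower; 2430 at an unadjusted p under 0.05) and 1 at day 14, which was lower (2446 at an unadjusted p under 0.05).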

How the results depend on the processing

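All alternatives were chosen before the data were examined. Of the 55 calls of named genes 28 held in each of the 16 fits without 1 array, and of the 28 list calls in the 2 drug comparisons and their difference 16 did. Without 1 array the counts ranged from 17 to 64 (higher at day 3), 85 to 213 (lower at day 3), 12 to 74 (higher at day 14), 17 to 66 (lower at day 14), 11 to 35 (both days), 0 to 110 (control livers between days) and 0 to 10 (difference of effects). The median of the cell cycle list at day 14 ranged from -0.011 to 0.229 and turned negative without treated replicate 3 of day 14. Apart from leaving out arrays, counts beyond 1.5 times were as follows. Fits of only the groups compared gave 29 genes higher at day 3, 8 higher and 15 lower at day 14, 6 at both days and 0 between control livers. Array weights gave 109 higher at day 3, 149 between control livers and 2 for the difference of effects. Centring gave 36 higher at day 3. Leaving out the lower part of the genes by mean value gave 87 higher and 75 lower at day 14, 51 at both days and 0 for the difference. An adjusted p under 0.01 left 11 higher and 72 lower at day 3, 6 and 7 at day 14, 5 at both days, 0 between control livers and 0 for the difference, and a 1.5-fold minimum left 36 higher at day 3. Replicate numbers are shared by the groups but do not pair the arrays: correlations of same-numbered arrays lay between -0.042 and 0.16, and 6 of 16 arrays correlated best with their own number on the same day. With the replicate block the counts were 49 and 176 at day 3, 32 and 42 at day 14, 31 at both days, 47 between control livers and 0 for the difference. Calls of named genes were lost by 22 in fits of only the groups compared, 11 with the block, 6 with centring, 3 with quantile normalization, and 1 each with array weights and with the intensity trend. With an estimated correlation 24 of the 28 list calls were lost. Except where smaller fits have fewer arrays and stricter thresholds pass fewer genes by construction, the cause was not tested. Signal near the bottom of the scale, where the median gene lies at 5.86, and near its top limits what can be seen.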

Other observations

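The test of feed intake was chosen after the lists had been seen, as were the genes and lists described here.

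Among the 26 genes called in the same direction at both days were several outside the fixed lists. Aqp9, a glycerol channel of hepatocytes, rose by 0.61 ± 0.13 (log2 ± SE) at day 3 and 0.85 ± 0.13 at day 14. Dio1, the deiodinase that activates thyroid hormone, changed by -1.10 ± 0.22 and -1.26 ± 0.22, the transporter gene Abcg2 by -1.11 ± 0.16 and -0.96 ± 0.16, Gbe1, the glycogen branching enzyme, by -0.86 ± 0.17 and -0.85 ± 0.17, and the cochaperone gene Fkbp4 by -0.86 ± 0.14 and -0.76 ± 0.14. Each passed limma's test at both days, with the highest adjusted p at 0.0422 (Gbe1 at day 14). Between control livers, 10 of the 37 lists passed camera and 2 of them with an estimated correlation. Those not yet described were macrophage markers (higher at day 14, adjusted p = 0.000142), amino acid catabolism (higher, 1.05e-07), periportal markers (higher, 0.0106), cholesterol synthesis (lower, 4.47e-08), ATF4 stress genes (lower, 0.00101), chaperones (lower, 0.00606) and glycolysis (lower, 0.0142). None had a member past the threshold over all genes, and with an estimated correlation their adjusted p were 0.531, 0.202, 0.296, 0.161, 0.21, 0.432 and 0.473.

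The fatty acid synthesis list stood lower by camera at both days, with 2 of 18 members falling at day 3 and 1 of 18 at day 14, and lost its calls with an estimated correlation (adjusted p = 0.176 and 0.18). For this list reduced feed intake is a candidate explanation, since feed intake is not given in the sources used here. Under it, 7 genes known to be induced by fasting (Pck1, Igfbp1, Ppargc1a, Cpt1a, Pdk4, Angptl4 and Fgf21) were taken to rise. Their mean change was 0.03 (SE 0.51) at day 3 and 0.61 (SE 0.51) at day 14. With this spread neither a rise nor its absence was shown, and the explanation stays open.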
